A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

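Newly synthesized RNA, labelled for 15 min with 4-thiouridine, was measured in 8 libraries, 2 each of parental U2OS cells, U2OS cells expressing SUPT3H from an introduced copy, wild-type mESC and mESC labelled Supt3h knockout. Per the labels' protocols, libraries were made from 15 ng of RNA cut to fragments of about 700 bp, with ribosomal RNA depletion and 12 PCR cycles in U2OS and without depletion and with 10 cycles in mESC, where reads were 50 bp long. The mESC medium held 3 µM CHIR99021 and 1 µM PD0325901. The lines therefore differ in library preparation as well as species, and no level was compared between them.

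The authors deposited whole-number counts per gene for the cell genes and, in separate tables, counts per S. pombe spike-in gene, per the file headers. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt 1.10, STAR 2.5.3a, HTSeq 0.6.1p1 and DESeq2 1.16.1 were used, with the builds hg38, mm10 and ASM294v2. The annotation release, whether introns were counted and the strand setting are not given in the sources used here, so counts of overlapping and antisense genes and of near-identical histone genes are uncertain. The authors deposited normalized counts too, which equal the counts divided by 1 factor per library, and log2 fold changes with p-values and adjusted p-values, per the file headers. The header of the U2OS fold change names no direction, and it was read as parental over SUPT3H-expressing from its sign against the counts. Columns of 4 other per-sample values were not used.

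Columns were tied to samples through the labels, and groups came from the labels alone. The designs, tests, gene lists and the rule for naming genes were fixed before the data were examined. Library factors were medians of ratios over the spike-in genes (0.897 to 1.23 in U2OS and 0.878 to 1.33 in mESC). Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 18106 of 31758 listed genes in U2OS and 14604 of 28585 in mESC. Each line was fitted alone with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with a prior count of 0.125 for fold changes and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are SUPT3H-expressing over parental and knockout over wild type. The prior degrees of freedom came out infinite in U2OS, so each gene there was judged by a spread shared over all genes, and the total was 8.35 in mESC. A change that rests on a single library can therefore pass in U2OS. Genes were also counted whose 95% interval of the log2 fold change lay within 2-fold.

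Gene lists, 35 for human and 41 for mouse, were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 5 members were tested, which left 34 and 38. Blood cell genes in both lines, and small nuclear RNA and two-cell-like genes in mESC, had too few. Total output was the sum of cell counts over the sum of spike-in counts, with an exact permutation test. A fold against counts of 0 used a floor of 3 counts over the group. Named genes were the targeted gene, the 10 protein-coding genes with the largest rise and fall among those past the threshold with a mean CPM of at least 1 and no overlap between groups, and up to 4 members with the smallest p in each called list or list the design asks about. Where fewer than 10 passed in a direction, the 5 with the smallest p were named as not passing. Windows held 20 neighbouring tested genes, and their shift was the median log2 difference of a library from the control mean, centred on the median of all genes, with 1 added to scaled counts. Runs were at least 3 neighbouring windows shifted by at least 0.3.

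The steps were tested on simulated counts with 200 changed genes per line. In U2OS 27% of 2-fold and 90% of 4-fold changes were recovered, with 6 false among 124 calls. The simulated U2OS counts gave every gene and both groups the same spread at a given level. In the real data the SD over genes of the log2 difference was 0.307 between the parental and 0.616 between the SUPT3H libraries. The 6 of 124 therefore do not describe the false calls among the real U2OS calls. In mESC 57% and 89% were recovered, with 3 false among 150 calls, but these counts gave every gene the same spread at its level, with 29208 total degrees of freedom against the 8.35 of the real fit, so they do not describe its power. Counts drawn for mESC with a spread that differed between genes, added after the data were seen, gave 8.18 degrees of freedom. There edgeR recovered 7% and 62%, with 4 false among 73 calls, and DESeq2 recovered 34% and 74%, with 35 false among 143. Alternatives were TMM and median-of-ratios scaling on the cell genes, total spike-in counts, no filter and a minimum count of 50, DESeq2 1.42.0 with the spike-in factors, robust empirical Bayes, a test against a fold of 1.5, the replicate number as a block, camera with an estimated correlation, fry, and leaving out each library. Where a group was left with 1 library, it was assumed to vary like the other group. Groups of 2 are too small for a test over other splits of the samples or for naming outlying libraries.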

Results

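Newly synthesized RNA was sequenced from human cells given an introduced copy of SUPT3H and from mouse cells labelled as lacking it. SUPT3H is a subunit of SAGA, a coactivator complex that modifies histones and helps the general transcription machinery to assemble at promoters. The series title sets the question whether a SAGA complex without SUPT3H can assemble and work while RNA polymerase II transcription stays largely undisturbed. RNA made during 15 min of 4-thiouridine labelling was purified, and labelled RNA of the fission yeast S. pombe was added as a spike-in, so that total output could be compared between libraries. There were 8 libraries in 4 groups of 2: parental U2OS cells and U2OS cells expressing SUPT3H from an introduced copy, and wild-type and Supt3h knockout mouse embryonic stem cells (mESC). U2OS is a human osteosarcoma line, and the mESC were E14 cells grown in serum with LIF and the inhibitors CHIR99021 and PD0325901, which hold them in the naive pluripotent state. The design text states 2 independent clones per cell line, and the labels do not tie a clone to a library.

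The U2OS libraries held 34933837 and 33282285 counts on human genes in parental cells and 28455026 and 29612907 in SUPT3H-expressing cells. The mESC libraries held 11830720 and 10882900 counts on mouse genes in wild-type cells and 9867352 and 14280454 in cells labelled knockout. Spike-in counts ranged from 1222400 to 1669962 in U2OS and from 778845 to 1192595 in mESC. Mitochondrially encoded genes took 0.246% to 0.295% of the U2OS counts and 0.633% to 0.721% of the mESC counts. In every mESC library the most abundant gene was Gm26917, with 6.17% to 8.25% of counts.

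Total newly synthesized RNA per spike-in did not separate the U2OS groups. Cell counts per spike-in count were 20.9 and 26.5 in parental U2OS (mean 23.7 ± 3.93, SD, n = 2) and 23.3 and 22.4 with SUPT3H (22.8 ± 0.612, SD, n = 2; exact permutation p = 1, two-sided). The log2 ratio of the group means was −0.04, and it was 0.13 without parental replicate 2. In mESC the ratios were 14.1 and 13.1 in wild-type cells (13.6 ± 0.684, SD, n = 2). The libraries labelled knockout had 12.7 and 12.0 (12.3 ± 0.491, SD, n = 2), a log2 difference of −0.15 (−0.13 without mitochondrial and the 10 most abundant genes). Its exact permutation p of 0.333 (two-sided) was the smallest that 2 against 2 libraries can give.

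**Figure D1:**
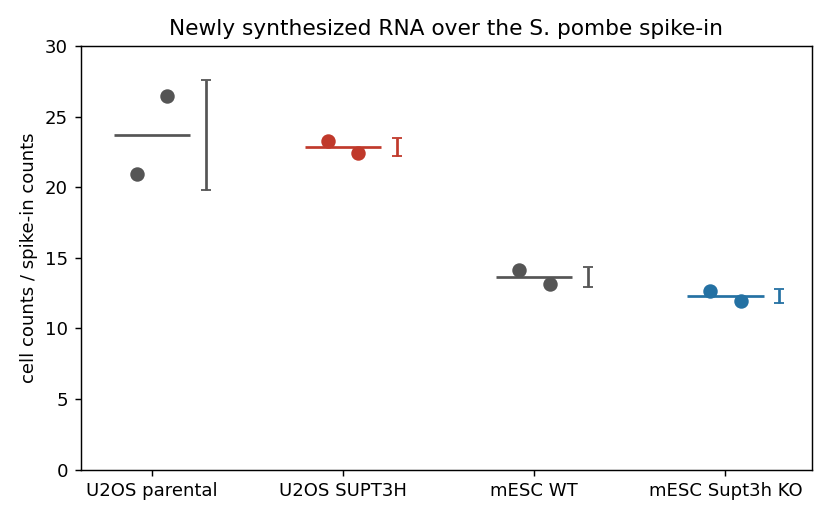
Counts on cell genes divided by counts on S. pombe spike-in genes (vertical axis, no unit) in each of the 8 libraries, by group; points are libraries, horizontal lines group means and brackets the mean ± 1 SD (n = 2). The U2OS SUPT3H libraries, 23.3 and 22.4, lay between the parental ones, 20.9 and 26.5, and the mESC libraries labelled knockout, 12.7 and 12.0, lay below the wild-type ones, 14.1 and 13.1.

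Of the 2 experiments, the first asked what an introduced copy of SUPT3H changes in U2OS. SUPT3H itself (ENSG00000196284, hg38 chromosome 6, 44809317 to 45377953, protein coding) had 59 and 45 counts in parental cells and 1286 and 1410 with the introduced copy. Scaled to the spike-in it rose from 48.2 ± 0.504 to 1440 ± 9.31 (SD, n = 2), 29.8-fold (log2 fold change 4.90, SE 0.41; edgeR adjusted p = 2.03e-28). The fold was nearly the same without either parental library, but the adjusted p was then 0.0615 (without replicate 1) or 0.0835 (without replicate 2). Of the 23 SAGA subunits tested, SUPT3H alone was called. The next smallest p was that of TRRAP, the large scaffold subunit, at −0.77 (SE 0.29, adjusted p = 0.195), and TRRAP lies in a stretch of chromosome 7 where most genes were lower. The SAGA list as a whole was not called (camera adjusted p = 0.896): its median was −0.13, while its mean of 0.07 and the test direction were positive. SUPT3H, at 4.90, is a member and pulls that mean up, and the list was not tested without it. None of the 15 TFIID subunits, which SAGA partly shares, was called (median −0.12, camera adjusted p = 0.582).

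The neighbours of SUPT3H on chromosome 6 were checked because the gene lies beside RUNX2, the master regulator of bone formation. Of 5 neighbours tested, RCAN2 (46220736 to 46491972), an inhibitor of calcineurin, rose 2.65-fold (log2 1.40, SE 0.36, adjusted p = 0.00706), from 235 ± 28.1 to 621 ± 313 scaled counts (SD, n = 2). Without SUPT3H replicate 1 it was 1.71-fold higher with an adjusted p of 1, without replicate 2 it was 0.0501, and with TMM scaling it was 0.151. RUNX2 stood at 0.57 (SE 0.31, adjusted p = 0.567), and its annotated span (45328157 to 45664349) overlaps that of SUPT3H, so reads could be shared if strand was not used in counting. The median of all 20 genes in the window holding these neighbours was 0.44 and 0.23 above the genome's in the SUPT3H libraries. None of the 13 osteoblast lineage genes was called (median 0.03, camera adjusted p = 0.896). TNFRSF11B, a decoy receptor that restrains osteoclasts, had 0.84 (SE 0.33, adjusted p = 0.228). The genes of its window on chromosome 8 were higher too, by medians of 0.58 and 0.42 in the SUPT3H libraries.

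Of the 18106 genes tested in U2OS, 307 rose and 151 fell in the SUPT3H-expressing cells. The labels list no U2OS cells given another introduced sequence. A change due to SUPT3H therefore cannot be told apart from one that came with deriving these cells, for single genes and for lists. After SUPT3H, the largest rises among protein-coding genes were in CPED1, DNAJC18, ADD2, PTPN7, SH2D2A, HRH2, WDR72, TRIM29 and HSPB7. ADD2 (chromosome 2, 70607618 to 70768225), the beta subunit of adducin in the membrane skeleton, rose 11.6-fold, from 73.0 ± 31.0 to 839 ± 241 scaled counts (log2 3.53, SE 0.40, adjusted p = 5.14e-16). SH2D2A (chromosome 1, 156806243 to 156816862), a T cell adapter protein, rose 7.48-fold, from 16.3 ± 1.31 to 122 ± 3.40 (adjusted p = 2.96e-08). HRH2 (chromosome 5, 175658030 to 175710756), the histamine H2 receptor, rose 7.43-fold, from 8 and 20 to 102 and 86 counts (adjusted p = 1.19e-07), but its parental libraries differed, and the fold was 4.66 without parental replicate 1 (adjusted p = 0.59) and 15.3 without replicate 2 (0.289). PTPN7, a tyrosine phosphatase best known from blood cells, rose 7.94-fold (adjusted p = 8.15e-11; 12.1-fold without parental replicate 2 and 4.86-fold without SUPT3H replicate 2) and WDR72 rose 7.32-fold (adjusted p = 1.22e-08; 4.15-fold without SUPT3H replicate 1). Some of these rises came mainly from a single SUPT3H library. CPED1 had 453 and 324 counts in parental cells but 659 and 12411 with SUPT3H, and without SUPT3H replicate 2 it was 2.05-fold higher (adjusted p = 0.767). TRIM29 (17 and 16 counts against 39 and 173; 2.81-fold and adjusted p = 0.193 without SUPT3H replicate 2) and HSPB7 (15 and 8 against 29 and 114; 3.04-fold and adjusted p = 0.229) leaned on the same library. DNAJC18 leaned on SUPT3H replicate 1, with 3 and 11 counts against 203 and 27 (4.12-fold and adjusted p = 0.101 without it, and 10.6-fold or 49.5-fold without parental replicate 1 or 2). With TMM scaling SUPT3H, ADD2 and SH2D2A kept an adjusted p under 0.05, and the other named rises did not (0.0703 for HRH2 to 0.198 for CPED1). The log2 fold changes of these others were no smaller with TMM, such as 2.98 against 2.89 for HRH2 and 4.27 against 4.23 for CPED1. By DESeq2 the adjusted p was 0.117 for TRIM29, 0.173 for CPED1 and 0.195 for DNAJC18.

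The falls were more even between the SUPT3H libraries. ANKRD62 (chromosome 18, 12093853 to 12129749) had 171 and 169 counts in parental cells and 0 and 1 with SUPT3H, a ratio of 295 with a 95% counting interval of 52.5 to 11670. ZNF597 (chromosome 16, 3432422 to 3443542), a zinc finger gene, had 107 and 123 counts against 0 and 1, a ratio of 199 with an interval of 35.4 to 7905. KLB (chromosome 4, 39406853 to 39451536), the beta-klotho coreceptor for endocrine fibroblast growth factors, fell 50.4-fold, from 302 ± 52.8 to 5.86 ± 0.412 scaled counts (adjusted p = 8.94e-25). ANXA10 (chromosome 4, 168092515 to 168187690), an annexin, fell 30.4-fold, from 280 ± 8.96 to 9.07 ± 0.224 (adjusted p = 5.14e-21). SHISA9 fell 12.8-fold (adjusted p = 1.46e-17), SEMA3A, a secreted axon guidance signal, fell 8.08-fold from 4823 ± 395 to 597 ± 210 (adjusted p = 1.78e-15), and DNAH11, a dynein heavy chain of cilia, fell 7.72-fold (adjusted p = 8.58e-12). PPP1R1C fell 10.5-fold (568 and 601 counts against 82 and 14; 38.2-fold and 6.05-fold without SUPT3H replicate 1 and 2), but its adjusted p was 0.106 by DESeq2 and 0.119 with TMM scaling, under which the other falls named here stayed past the threshold. Counting intervals cover counting error only, since PCR copies were not removed by molecular identifiers.

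**Figure D2:**
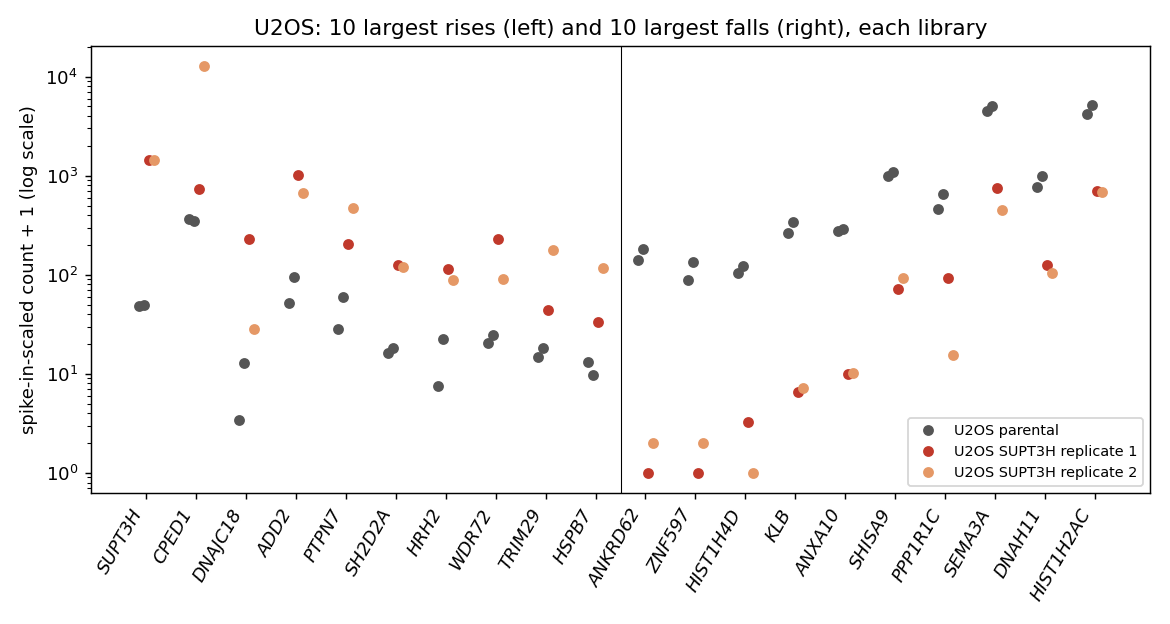
Spike-in-scaled count plus 1 (vertical axis, log scale, no unit) of the 10 protein-coding genes with the largest rise (left) and the 10 with the largest fall (right) in U2OS; each point is a library, grey for parental cells, red and orange for SUPT3H replicates 1 and 2. SUPT3H itself moved from a mean of 48.2 to 1440, KLB from 302 to 5.86, and CPED1 was carried by replicate 2, with 12411 counts against 659 in replicate 1.

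Replication-dependent histone genes were the group that moved most in U2OS. All 37 tested members had negative log2 fold changes, with a median of −0.98 (fold 1.97), and 14 fell (24 adjusted over the list alone; camera adjusted p = 2.55e-36, adjusted p = 0.992 with an estimated correlation). HIST1H2AC (chromosome 6, 26124145 to 26139116) fell 6.75-fold, from 4669 ± 727 to 691 ± 8.79 scaled counts (SD, n = 2; adjusted p = 4.04e-13). HIST1H4D (26188765 to 26189076) had 127 and 112 counts against 2 and 0, a ratio of 104 with a counting interval of 28.4 to 860. HIST1H2AE (26216975 to 26217483) had 51 and 30 counts against 0 and 0, at least 23.4-fold lower with a floor of 3 counts over the group, and the list median was unchanged with it at that bound. HIST1H2BG had 49 and 33 counts against 0 and 1 (ratio 71.1, interval 12.4 to 2840). With TMM scaling the adjusted p was 0.0695 for HIST1H2AE and 0.059 for HIST1H2BG. Of the 14 calls, 5 remained with TMM scaling, 5 and 4 without SUPT3H replicate 1 and 2, 12 by DESeq2 and 0 without either parental library. The fall was placed on the genome: the 33 histone genes of the chromosome 6 cluster (26017085 to 27837947) had a median of −1.11 and held all 14 called genes, and the 4 histone genes elsewhere had a median of −0.33 and no call. The 20 other genes between the first and last of those histone genes had a median of −0.34, with 4 that fell. Outside the cluster, the 60 genes of chromosome 6 from 7541575 to 21595593 were lower too, by medians of −0.40 and −0.48 in SUPT3H replicates 1 and 2. How far the fall of the histone genes follows that of the region was not tested. Histone genes are near-identical copies, so counts of single members are uncertain.

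Other lists were lower as groups with few single calls. The median of all genes was −0.06, and it moved to −0.22 without parental replicate 1 and 0.15 without parental replicate 2. Part of the swing of a list median without a parental library is therefore shared by all genes. With TMM scaling the medians were −0.29 for S-phase and E2F targets, −0.22 for G2 and M phase and −0.33 for cholesterol synthesis. All but 1 of the 40 S-phase and E2F target genes had negative values, with a median of −0.36 (−0.09 without parental replicate 2) and no call by edgeR (camera adjusted p = 3.69e-05, adjusted p = 0.992 with an estimated correlation). TYMS, which makes thymidylate for DNA synthesis, had −0.96 (SE 0.32, edgeR adjusted p = 0.0853) and MCM7, of the replicative helicase, −0.89 (SE 0.32, edgeR adjusted p = 0.138), and DESeq2 called both as lower (0.0193 and 0.0405). Both genes lie in windows where the neighbouring genes were lower too, by medians of −0.49 and −0.49 for TYMS and −0.85 and −0.50 for MCM7 in the SUPT3H libraries. TK1 and RRM2, also in nucleotide supply, had −0.78 and −0.84 (edgeR adjusted p = 0.290 and 0.325), and their windows were at 0.12 and −0.29 for TK1 and at 0.04 and −0.08 for RRM2. The 32 genes of G2 and M phase had a median of −0.29 and no call by edgeR (camera adjusted p = 0.00367, adjusted p = 0.992 with an estimated correlation). The median was −0.55 without parental replicate 1, −0.02 without parental replicate 2 (camera adjusted p = 0.0853) and −0.19 without SUPT3H replicate 2 (0.185). DESeq2 called the mitotic checkpoint gene MAD2L1 as lower (−0.90, adjusted p = 0.0476; 0.191 by edgeR). The 22 cholesterol synthesis genes had a median of −0.40 (−0.62 and −0.12 without parental replicate 1 and 2) and no call (camera adjusted p = 0.000324, adjusted p = 0.992 with an estimated correlation); MSMO1, a sterol methyl oxidase, had −0.80 (SE 0.33, adjusted p = 0.262). The 9 chondrocyte genes had a median of −0.33 (camera adjusted p = 0.0368, adjusted p = 0.992 with an estimated correlation; 0.072 without parental replicate 1 and 0.272 without SUPT3H replicate 2). Without parental replicate 2 the median was −0.20, and it was −0.69 and −0.12 without SUPT3H replicate 1 and 2. ACAN, the cartilage proteoglycan aggrecan, fell 2.60-fold by edgeR (adjusted p = 0.0326; 0.0714 by DESeq2, and 0.0995 and 0.533 without SUPT3H replicate 1 and 2), and COL11A1, a cartilage collagen, was called as lower by DESeq2 (−0.95, adjusted p = 0.0387; 0.116 by edgeR). The 19 NF-kB and inflammation genes had a median of −0.27 (camera adjusted p = 0.0387, adjusted p = 0.992 with an estimated correlation; 0.0797 without parental replicate 1 and 0.677 without SUPT3H replicate 2), which was −0.09 without parental replicate 2 and −0.74 without SUPT3H replicate 1. In that list TRAF1, a signalling adapter, fell from 1688 ± 308 to 675 ± 38.3 scaled counts (SD, n = 2; adjusted p = 0.00632) and the chemokine CCL2 rose 2.46-fold (adjusted p = 0.0266), and DESeq2 also called the cytokine IL11 as lower (−0.95, adjusted p = 0.043; 0.164 by edgeR). Without SUPT3H replicate 1 the adjusted p was 0.753 for TRAF1 and 0.875 for CCL2, and without replicate 2 it was 0.584 for TRAF1. The 79 ribosomal protein genes had a median of −0.13 and 1 call, RPL3L, a muscle form, with 21 and 20 counts against 8 and 0 (adjusted p = 0.0387; 0.966 without SUPT3H replicate 2). Their camera adjusted p was 0.0368 (adjusted p = 0.992 with an estimated correlation), but 0.051 with TMM scaling, 0.0929 with a minimum count of 50, 0.0543 without parental replicate 2 and 0.984 without SUPT3H replicate 1. The median was −0.07 with TMM, −0.27 and 0.01 without parental replicate 1 and 2, and −0.0041 and −0.28 without SUPT3H replicate 1 and 2.

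Lists that were higher in U2OS were fewer. Their medians without a parental library also carry the shift of all genes, to −0.22 without parental replicate 1 and 0.15 without parental replicate 2. Of 14 MHC class I and II genes, 13 had positive values, with a median of 0.41, and HLA-DPB1 (2 and 7 counts against 33 and 18) and HLA-DPA1 (10 and 7 against 34 and 22) rose (camera adjusted p = 0.000324, adjusted p = 0.992 with an estimated correlation; 0.105 without SUPT3H replicate 1). The median was 0.24 and 0.64 without parental replicate 1 and 2, and 0.19 and 0.63 without SUPT3H replicate 1 and 2. HLA-DPB1 and HLA-DPA1 overlap each other on chromosome 6 and had at most 34 counts in any library. Without SUPT3H replicate 1 their adjusted p was 0.253 and 0.504, and DESeq2 gave 0.221 for HLA-DPA1 and none for HLA-DPB1, which was 3.60-fold and 15.8-fold higher without parental replicate 1 and 2. The 16 HOX genes had a median of 0.48, and HOXA3, a patterning transcription factor, rose 3.10-fold from 27.9 ± 10.8 to 85.7 ± 6.53 scaled counts (adjusted p = 0.00767; 0.0648 without SUPT3H replicate 1 and 0.0791 with TMM scaling). Their camera adjusted p was 0.00661 (adjusted p = 0.992 with an estimated correlation), and it was 0.0853 without parental replicate 2 and 0.247 without SUPT3H replicate 1. The median was 0.28 without parental replicate 1, and 0.26 and 0.74 without SUPT3H replicate 1 and 2. The 22 mitochondrially encoded genes had a median of 0.21 (0.08 without parental replicate 1) and no call (camera adjusted p = 0.023, adjusted p = 0.992 with an estimated correlation; 0.082 without parental replicate 2 and 0.247 without SUPT3H replicate 1). Of the 10 lists called in U2OS, fry called none (smallest adjusted p 0.436). The other 24 tested lists had camera adjusted p between 0.127 and 0.976 and medians between −0.33 and 0.17.

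Neighbouring genes moved together in the SUPT3H libraries. Over 906 windows of 20 neighbouring genes, 132 had a median shifted by at least 0.3 (log2) from the genome's in SUPT3H replicate 1 and 181 in replicate 2, 53 of them the same way in both, against 0 between the parental libraries. In both SUPT3H libraries the 200 genes of chromosome 7 from 80312574 to 107717809 were lower, by medians of −0.61 and −0.57; the stretch holds SEMA3A, TRRAP, MCM7 and TAF6. The 100 genes of chromosome 8 from 26748150 to 42541926 were lower by −0.53 and −0.74, and the 80 genes of chromosome 6 from 34576258 to 42868560 were higher by 0.50 and 0.44. Other stretches moved in a single library. In replicate 1 the 200 genes of chromosome 1 from 59814786 to 108809526 were lower by −0.55, against 0.01 in replicate 2. In replicate 2 the 280 genes of chromosome 11 from 60515413 to 75594665 were higher by 0.61, against 0.01 in replicate 1. On chromosome 2, 300 genes from 165794857 to 219250337 were lower by −0.52 in replicate 2, against 0.04 in replicate 1. Further runs of chromosome 2 between 55547292 and 242160153 were lower in replicate 2 too, by −0.36 to −0.47, against −0.01 to 0.11 in replicate 1. Some other named genes lay in windows shifted by at least 0.3 in 1 or both SUPT3H libraries. Among them were ANKRD62 (−0.28 and −0.45 in SUPT3H replicate 1 and 2), ANXA10 and MSMO1 (−0.31 and −0.37), MAD2L1 (−0.41 and −0.39), IL11 (−0.31 and −0.21) and HOXA3 (0.60 and 0.22). HIST1H2AC, HIST1H2AE, HIST1H2BG and HIST1H4D shared a window at −1.05 and −1.28, whose median includes these histone genes themselves. The windows of COL11A1 (−0.57 and 0.01), PPP1R1C (−0.01 and −0.53) and TRIM29 (0.14 and 0.60) reached 0.3 in a single library, as did those of ANKRD62, IL11 and HOXA3. Windows shifted in either library held 28.4% of the genes and 42.0% of the called genes (191 of 455). Without the genes of these windows 251 genes were called, 192 of them higher.

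**Figure D3:**
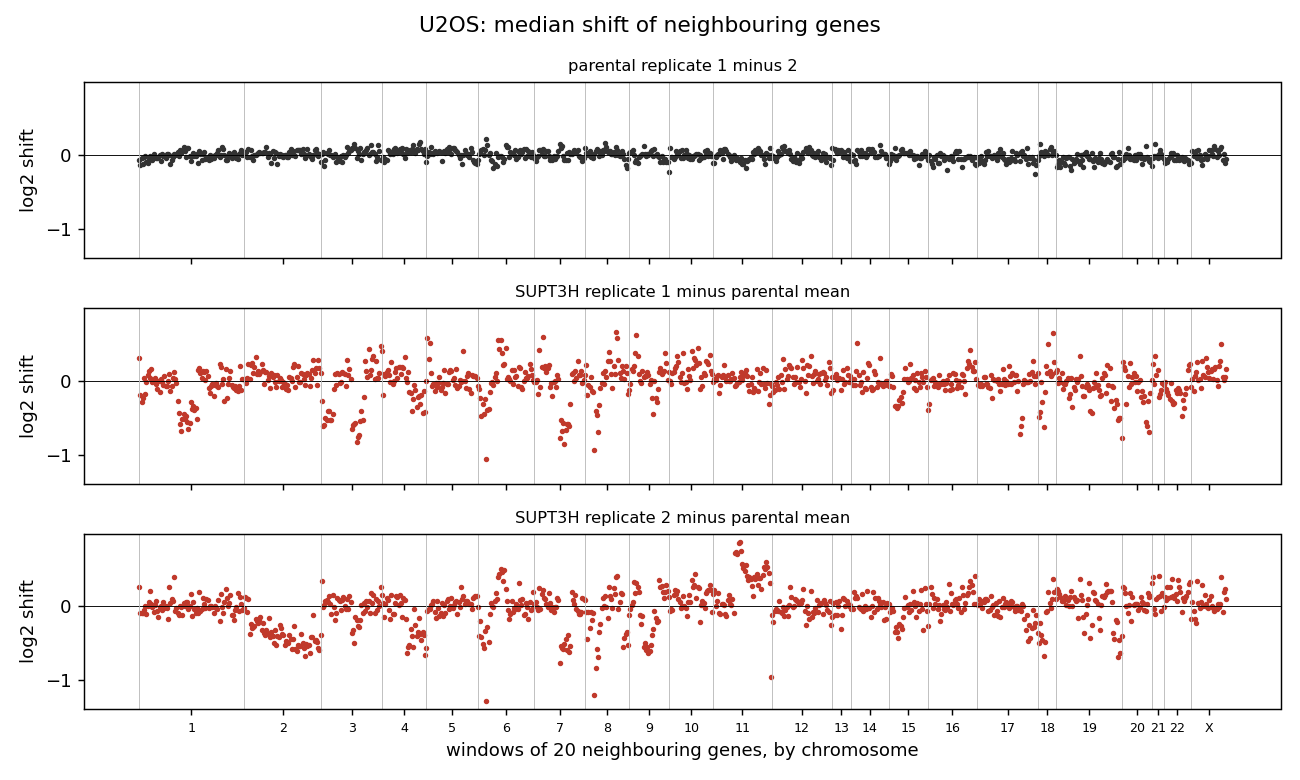
Median log2 shift (vertical axis) of windows of 20 neighbouring genes along the chromosomes (horizontal axis), each point a window, centred on the median of all genes; the panels show the difference between the parental libraries and each SUPT3H library against the parental mean. The parental panel has 0 windows shifted by 0.3 or more, and the SUPT3H panels have 132 and 181.

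By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and spike-in scaling, 458 of 18106 genes changed in U2OS, of which 67.0% were higher, and 307 of the higher and 148 of the lower changed at least 2-fold. The test uses a spread common to both groups, but the SUPT3H libraries differed more from each other than the parental ones did. The SD over genes of the log2 difference was 0.616 against 0.307, so adjusted p-values may be too small where the SUPT3H libraries differ. The libraries of the groups did not overlap for 436 of the 458, which were selected on the same difference, and for 33.8% of all genes tested, where chance gives 33.3%. TMM scaling on the human genes called 55 genes (25 higher, 30 lower, 45.5% higher), 52 of them shared. At an unadjusted p under 0.05, however, edgeR gave 3159 genes with TMM and 1791 with spike-in scaling. The log2 fold change of SUPT3H was 4.94 with TMM and 4.90 with spike-in scaling, but its edgeR adjusted p with TMM was 0.0074. Fewer calls with TMM therefore need not mean smaller changes. DESeq2 with the spike-in factors called 339 (183 higher, 156 lower), 254 of them shared. Without either parental library no gene was called (1332 and 1106 at an unadjusted p under 0.05), and 220 or 259 were called without SUPT3H replicate 1 or 2. The 95% interval of the log2 fold change lay within 2-fold for 9360 genes (51.7%), and for 408 to 6521 with a library left out. The median log2 fold change over all genes was −0.06 with spike-in scaling and 0.01 with TMM; it was 0.15 without parental replicate 2. The authors' deposited table gives 318 changed genes of 16981 in U2OS (169 higher and 149 lower with SUPT3H, taking its unlabelled fold as parental over SUPT3H), of which 240 were among the edgeR calls and 313 among the DESeq2 calls made here.

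The other experiment asked what loss of Supt3h changes in mESC. The targeted gene, listed as Supt3 (ENSMUSG00000038954, mm10 chromosome 17, 44777152 to 45119290), had 1797 and 1588 counts in wild-type libraries and 1674 and 2520 in those labelled knockout. Its scaled counts of 1828 ± 164 and 1902 ± 5.69 (SD, n = 2) did not differ by more than the test could show (log2 0.06, SE 0.13, adjusted p = 0.876). The labels do not state which part of the gene was deleted, and counts over a whole gene need not fall when a part is lost, so this value does not check the knockout label. Below, directions rest on the label. Of 24 SAGA subunits none was called. Negative values were found for 21, with a list median of −0.22 (camera adjusted p = 0.0978, and 0.00647 without the low-count filter). Of these, Taf5l had −0.39 (SE 0.13, adjusted p = 0.402). None of 15 TFIID subunits was called, and 13 had negative values (median −0.15, camera adjusted p = 0.413). The 13 subunits of ATAC, another acetyltransferase complex that shares parts with SAGA, all had negative values, with a median of −0.30 and no call (camera adjusted p = 0.012, adjusted p = 0.70 with an estimated correlation; 0.0575 without wild-type replicate 2 and 0.146 without knockout replicate 2).

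Genes that define the pluripotent state were not called. The 24 naive pluripotency genes had a median of −0.17 (camera adjusted p = 0.400; 0.0486 without wild-type replicate 2); Zfp42, also known as Rex1, had 7572 ± 965 scaled counts in wild-type cells and 5952 ± 406 in those labelled knockout (SD, n = 2; log2 −0.35, SE 0.14, adjusted p = 0.426), and Klf2 had −0.41 (SE 0.16, adjusted p = 0.427). The 15 core pluripotency genes had a median of −0.14 (camera adjusted p = 0.368), with Pou5f1, which encodes Oct4, at −0.27 (SE 0.15, adjusted p = 0.506). Sall1 had −0.74 (SE 0.18, adjusted p = 0.295) and passed when adjusted over the list alone. The 12 formative and primed pluripotency genes had a median of −0.22 (camera adjusted p = 0.681; 0.0148 without knockout replicate 2); in that list Otx2 had 36 and 39 counts against 1 and 28, and Lef1 had 178 and 189 against 122 and 671. The 5 neighbours of Supt3 had a median of 0.07 and no call (camera adjusted p = 0.274; 0.0431 without knockout replicate 1), with Runx2, which overlaps Supt3, at 10 and 16 counts against 11 and 128.

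Proliferation and biosynthesis genes were lower as groups in the libraries labelled knockout, with no single call over all genes by edgeR and 1, Uhrf1, by DESeq2. Short genes were lower in general: those spanning up to 4.66 kb had a median of −0.21, and those of at least 145 kb 0.05. Neither these lists nor the higher ones below were compared with genes of like length, so how far their medians follow gene length was not tested. All 39 S-phase and E2F target genes had negative values, with a median of −0.47, and 28 were lower when adjusted over the list alone (camera adjusted p = 1.36e-17; adjusted p = 0.70 with an estimated correlation). Uhrf1, which recruits DNA methyltransferase at replication forks, had 1379 ± 89.8 and 795 ± 69.1 scaled counts (SD, n = 2; log2 −0.79, SE 0.14; adjusted p = 0.193 by edgeR and 0.00571 by DESeq2), and Cdc6, which loads the replicative helicase, had −0.69 (SE 0.15, adjusted p = 0.284). The 32 G2 and M phase genes had a median of −0.25 (camera adjusted p = 0.00106, adjusted p = 0.70 with an estimated correlation), with Cdk1, the mitotic kinase, at −0.52 (SE 0.12, adjusted p = 0.294). All 32 MYC target and nucleolar genes had negative values, with a median of −0.30, or −0.16 without wild-type replicate 1 (camera adjusted p = 4.73e-05, adjusted p = 0.831 with an estimated correlation), with Nop56, a factor in ribosomal RNA processing, at −0.67 (SE 0.15, adjusted p = 0.293). Of 81 ribosomal protein genes, 80 had negative values, with a median of −0.29 (camera adjusted p = 8.54e-08, adjusted p = 0.831 with an estimated correlation; 0.0554 without knockout replicate 2). It was −0.18 without wild-type replicate 1 and −0.18 without knockout replicate 2. With TMM scaling the median was −0.16 for G2 and M phase, −0.20 for MYC targets and −0.19 for ribosomal proteins. The 27 hypoxia and glycolysis genes had a median of −0.39 (camera adjusted p = 0.00106, adjusted p = 0.831 with an estimated correlation), with Pkm, a glycolytic enzyme, at −0.39 (SE 0.12, adjusted p = 0.387). The 26 integrated stress response genes had a median of −0.36 (camera adjusted p = 0.0109, adjusted p = 0.831 with an estimated correlation; 0.0523 without knockout replicate 2); Psat1 and Slc7a3, in amino acid synthesis and uptake, were lower when adjusted over the list alone (−0.64 and −0.95), while Atf3, a stress-induced transcription factor, had 1.34 (SE 0.44, adjusted p = 0.402). The 50 histone genes had a median of −0.34 (camera adjusted p = 0.00478, adjusted p = 0.851 with an estimated correlation), but −0.02 and an adjusted p of 0.969 without wild-type replicate 1, a median of −0.64 without wild-type replicate 2, and an adjusted p of 0.203 without knockout replicate 2.

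The lists that were higher in the libraries labelled knockout were p53 targets, neuronal, TGF-beta target and epithelial genes. Of 23 p53 targets, 16 had positive values, with a median of 0.21, and 3 were higher when adjusted over the list alone (camera adjusted p = 1.32e-05, adjusted p = 0.70 with an estimated correlation). Among them, Plk2 had 0.83 (SE 0.17, adjusted p = 0.274), Eda2r 0.51 (SE 0.13, adjusted p = 0.307) and the proapoptotic Bbc3 1.03 (SE 0.28, adjusted p = 0.325). The 19 neuronal genes had a median of 0.30, or 0.17 without knockout replicate 2 (camera adjusted p = 0.00106, adjusted p = 0.70 with an estimated correlation), with Syt1, a synaptic vesicle protein, at 49 and 30 counts against 89 and 309 (adjusted p = 0.284 by edgeR and 0.00407 by DESeq2), and with Pax6 in the other direction at 31 and 19 counts against 14 and 13 (adjusted p = 0.448). The 20 TGF-beta targets had a median of 0.10 (camera adjusted p = 0.00738, adjusted p = 0.831 with an estimated correlation; 0.0763, with a median of −0.07, without wild-type replicate 2 and 0.0926 without knockout replicate 2), with Ltbp2 at 13 and 20 counts against 47 and 82. Their median was 0.20 with TMM, 0.05 with a minimum count of 50, 0.31 without wild-type replicate 1 and 0.27 without knockout replicate 1. The 11 epithelial genes had a median of 0.52 (camera adjusted p = 0.00869, adjusted p = 0.831 with an estimated correlation), 0.83 without knockout replicate 1, but −0.39 and an adjusted p of 0.938 without knockout replicate 2, in which Cdh3 had 282 counts against 39 in knockout replicate 1. Of the 12 lists called in mESC, fry called none (smallest adjusted p 0.231). The other 26 tested lists had camera adjusted p between 0.0522 and 0.821 and medians between −0.26 and 0.21. The median of all genes was −0.12 with spike-in scaling and −0.02 with TMM, and none of the medians of the called lists changed sign with TMM.

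**Figure D4:**
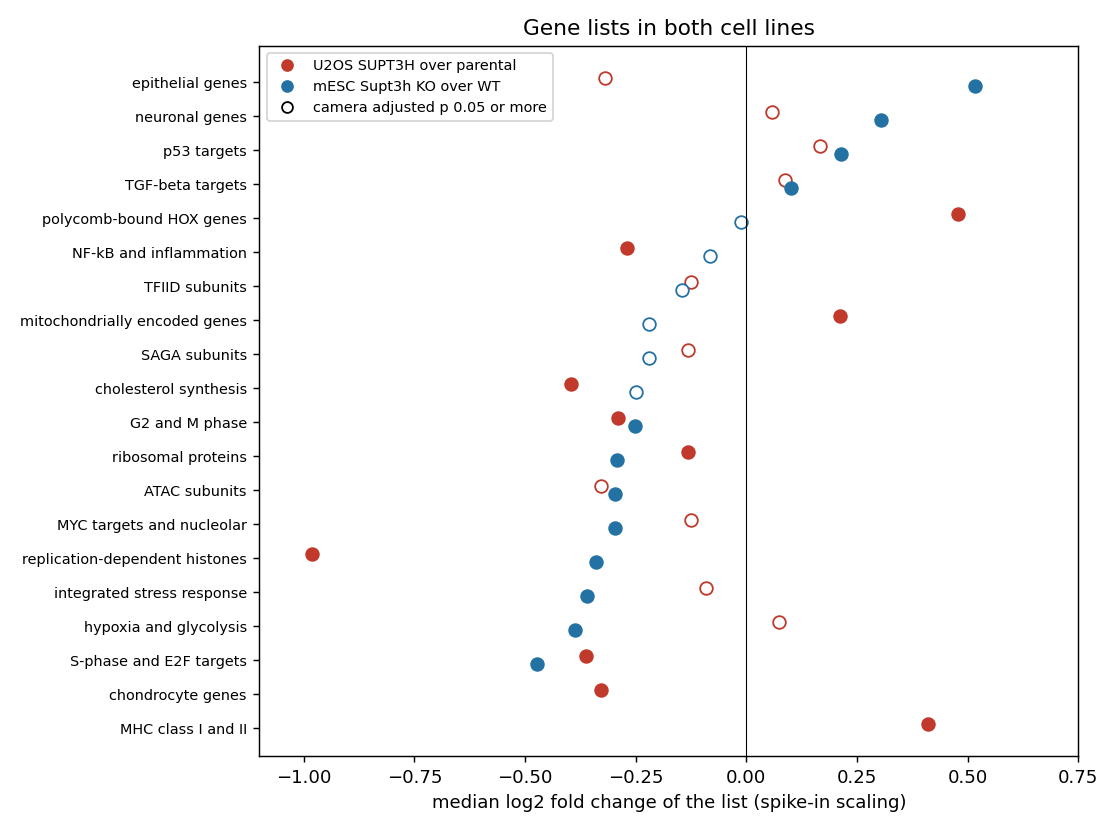
Median log2 fold change (horizontal axis, spike-in scaling) of the gene lists called in either cell line and of SAGA and TFIID subunits, red for U2OS with SUPT3H over parental cells and blue for mESC labelled knockout over wild type; filled points have a camera adjusted p under 0.05 with the preset correlation. Histone genes in U2OS were at −0.98, and S-phase and E2F targets were at −0.36 in U2OS and −0.47 in mESC.

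No single gene of the 14604 tested in mESC passed edgeR's quasi-likelihood test without a replicate block (smallest adjusted p 0.167; 1598 genes at an unadjusted p under 0.05). With the replicate number as a block edgeR called 5 genes, with Ano3, Anks1b, Plxdc2 and Samd12 higher and Gna14 lower, and 2009 genes had an unadjusted p under 0.05. The protein-coding genes with the smallest p whose libraries did not overlap were higher for Plxdc2, Samd12, Ano3, Anks1b and Atxn1 and lower for Gna14, Dner, Kit, Ebf1 and Abcc1. Ano3 (chromosome 2, 110655201 to 110950923), a membrane protein of the anoctamin family, had 548 ± 114 and 2308 ± 859 scaled counts (SD, n = 2; log2 2.07, SE 0.26, adjusted p = 0.167). Plxdc2 (chromosome 2, 16356304 to 16755839) had 1072 ± 256 and 2989 ± 82.8 (log2 1.48, SE 0.17, adjusted p = 0.167). Kit (chromosome 5, 75574916 to 75656722), the stem cell factor receptor, had 8063 ± 726 and 4564 ± 287 (log2 −0.82, SE 0.13, adjusted p = 0.170), and Gna14 (chromosome 19, 16435667 to 16610818) had 493 ± 129 and 151 ± 38.5 (log2 −1.69, SE 0.25, adjusted p = 0.170). All of these 10 genes passed DESeq2 with the same spike-in factors, which called 88 genes (60 higher, 28 lower); in counts simulated for mESC with a like spread between genes, 35 of 143 DESeq2 calls were false. Without wild-type replicate 1 edgeR called 17 genes (13 higher, 4 lower), and it called 1 without wild-type replicate 2, 0 without knockout replicate 1 and 1 without knockout replicate 2. Fold changes went with the length of the gene: genes spanning at least 145 kb had a median of 0.05 and those up to 4.66 kb −0.21. The 95% interval lay within 2-fold for 9398 genes (64.4%). The authors' deposited table gives 124 changed genes of 11959 in mESC (79 higher, 45 lower), of which 82 were among the DESeq2 calls made here.

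If both experiments read out the amount of SUPT3H, their fold changes would be expected to mirror each other. Across 10349 genes with the same symbol in both species, the fold changes, each turned to read more over less SUPT3H by the labels, had a Pearson correlation of −0.147 and a Spearman correlation of −0.138, and 39.2% had the same sign. The Pearson value was −0.06 without SUPT3H replicate 1 and −0.04 without knockout replicate 2. Genes are not independent replicates, so no p-value is given for a correlation across them. No gene was called by edgeR in both lines (192 and 0 of the shared genes). DESeq2 called 186 and 64 of the shared genes, with 2 in both where 1.15 would be met by chance (Fisher's exact test p = 0.320). These were PLXDC2 and PROS1, an anticoagulant protein, both higher in the changed cells of each line. PLXDC2 went from 2048 ± 114 to 4519 ± 2022 scaled counts in U2OS (SD, n = 2), and its DESeq2 log2 fold change in mESC was 1.48. For PROS1 the DESeq2 log2 fold changes were 1.52 in U2OS and 0.94 in mESC.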

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

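For 3 of the gene lists tested in both lines, and for both genes that DESeq2 called in both, every SUPT3H-expressing U2OS library and every mESC library labelled knockout lay on the same side of both of its controls, although SUPT3H was raised in the first line and its gene was targeted in the other. Read as more over less SUPT3H by the labels, the lines went opposite ways. The difference between the lines was not tested. Many mESC lists lay below both controls, also uncalled ones such as TFIID subunits and oxidative phosphorylation genes, and the mESC median of all genes was −0.12. How many lists would coincide by chance was not worked out. Both genes were picked for being called in both lines, so their separation is no further support. The S-phase and E2F targets had a median log2 fold change of −0.363 in U2OS and −0.474 in mESC and were called in both lines. Cholesterol synthesis genes had −0.397 and −0.250, with a camera adjusted p of 0.000324 in U2OS and 0.0522 in mESC. The p53 targets had 0.167 and 0.214, with a camera adjusted p of 0.156 in U2OS and 1.32e-05 in mESC. None of these calls held with an estimated correlation. PLXDC2 had DESeq2 log2 fold changes of 1.142 in U2OS and 1.479 in mESC, and PROS1 had 1.516 and 0.9385. Relative to the mean of all 4 libraries of a line, the medians of the S-phase and E2F targets were −0.06 and 0.38 in parental and −0.15 and −0.19 in SUPT3H-expressing U2OS libraries, and 0.26 and 0.20 in wild-type mESC and −0.18 and −0.31 in those labelled knockout.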

How the results depend on the processing

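Bias-adjusted quasi-likelihood, DESeq2 with factors from the cell genes, and leaving out shifted windows were added after the data were seen. In U2OS the count of 458 changed genes became 55 with TMM and 51 with median-of-ratios scaling on the cell genes, 178 against a fold of 1.5, 844 by DESeq2 with factors from the cell genes and 251 without shifted windows. It stayed within 1.5 times under total spike-in counts (459), no filter (471), a minimum count of 50 (332), DESeq2 with spike-in factors (339) and robust fitting (424). The 10 called lists became 0 with an estimated correlation and 0 by fry. In mESC the count of 0 became 4 without a filter, 88 by DESeq2 and 128 by DESeq2 with factors from the cell genes, and the 12 called lists became 19 without a filter, 0 with an estimated correlation and 0 by fry. The cause was not tested, except that leaving out windows tests fewer genes.

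Replicate numbers were checked for pairing: deviations of same-numbered libraries correlated at −0.004 in U2OS and 0.12 in mESC over 2 pairs. Such a value over all genes does not exclude pairing in mESC, where same-numbered libraries moved together in stretches of chromosomes 14 and 17. On chromosome 14 knockout replicates 1 and 2 were shifted by 0.37 and −0.18, and wild-type replicate 1 minus 2 was 0.53. On chromosome 17 the knockout shifts were −0.51 and 0.37, and the wild-type difference was −0.79. With the replicate block 406 genes were called in U2OS (377 shared) and 5 in mESC, where Ano3, Anks1b, Plxdc2 and Samd12 were higher and Gna14 was lower (adjusted p 0.00237 to 0.0465).

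With each library left out in turn, changed genes ranged from 0 to 259 in U2OS and from 0 to 17 in mESC, where a group of 1 is assumed to vary like the other. Genes held within 2-fold ranged from 408 to 6521 and from 7425 to 7922, and called lists from 6 to 9 and from 8 to 18. The median of all genes ranged from −0.219 to 0.149 in U2OS and from −0.167 to −0.0322 in mESC, and the log2 yield from −0.213 to 0.127 and from −0.197 to −0.094. SUPT3H ranged from 4.89 to 4.91 and Supt3 from −0.0326 to 0.154. The correlation between lines ranged from −0.168 to −0.0449.

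Some results turned direction, for lists that of the camera test, and of these only the mESC histones had been past the threshold. CDC5L in U2OS was 0.0192 with TMM, 0.0107 with median-of-ratios scaling and −0.192 to 0.124 with a library left out, and ENPP4 ranged from −0.339 to 0.147. The SAGA list median in U2OS ranged from −0.290 to 0.0229 and turned direction without SUPT3H replicate 2 (−0.192). In mESC the ranges were −0.565 to 1.69 for Cdh3, −0.510 to 1.36 for Lef1, −0.160 to 2.77 for Runx2 and −0.228 to 0.441 for Spats1. List medians in mESC ranged from −0.640 to −0.0204 for histones, from −0.285 to −0.0213 for core pluripotency and from −0.480 to 0.105 for formative and primed pluripotency, which was −0.282 with a minimum count of 50. The correlation without SUPT3H is no test of that gene, since its symbol differs between the species. At this depth and with 2 libraries per group, the median SE of a log2 fold change was 0.36 in U2OS and 0.24 in mESC.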

Other observations

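The tests of chance order, a technical trend and an effect of SUPT3H on regions in U2OS, that of a response following the level of SUPT3H, and the correlations given span or mean count alone, were chosen only after their results were seen. In mESC, DESeq2 with the spike-in factors called 88 genes where edgeR called none, and all 88 had an unadjusted edgeR p under 0.05. Of these, 79 were protein coding and 7 were lincRNA or antisense genes. The 60 higher genes had a median span of 157 kb and the 28 lower ones of 100 kb, against 26.5 kb for all genes tested, and 45 and 8 of them changed at least 2-fold. In U2OS the 183 higher and 156 lower DESeq2 calls had median spans of 151 kb and 42.6 kb, against 34.1 kb. By edgeR, 62 of 1686 lincRNA genes rose in U2OS and 20 fell, and 23 of 1518 antisense genes rose and 8 fell, against 197 and 114 of 13717 protein-coding genes. Antisense counts depend on whether strand was used in counting, which is not given in the sources used here.

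Single members of lists that were not called passed the threshold in U2OS, and they are named after their values were seen. Among ERK feedback genes, SPRY4 had 13 and 13 counts in parental cells and 0 and 1 with SUPT3H (adjusted p = 0.00244). IL17RD, also a brake on growth factor signalling, rose from 146 ± 11.6 to 459 ± 73.8 scaled counts (SD, n = 2; edgeR adjusted p = 0.000892), and the receptor EPHA4 rose from 1555 ± 411 to 3707 ± 120 (edgeR adjusted p = 0.00717). With TMM scaling EPHA4 alone of these stayed past the threshold (0.0321). Of the interferon response genes, OAS1 rose from 4 and 2 counts to 24 and 26 (edgeR adjusted p = 0.000123; 0.0661 with TMM). IFI44 fell from 72 and 40 to 22 and 5 (edgeR adjusted p = 0.00935; 0.262 with TMM and 0.194 by DESeq2). F3, the tissue factor that starts blood clotting, rose from 119 and 96 counts to 533 and 107, carried by SUPT3H replicate 1 (adjusted p = 1 without it). THBS1, which encodes thrombospondin, fell from 34167 ± 3983 to 17630 ± 2049 scaled counts (SD, n = 2; edgeR adjusted p = 0.0377; 0.0682 with TMM and 0.195 with the replicate block). The neuronal list, with a median of 0.06, held 4 calls of 22 genes, the most of these lists. Beside the axon guidance signal SEMA3A, which fell, the scaffold gene DLG2 rose from 5735 ± 677 to 11697 ± 69.4 scaled counts (SD, n = 2; edgeR adjusted p = 0.0302; 0.0382 with TMM and 0.0902 with the replicate block). MAP2, of the dendritic cytoskeleton, rose from 556 and 474 counts to 1698 and 780 (edgeR adjusted p = 0.00165; 0.165 with TMM), and it was 1.66-fold higher without SUPT3H replicate 1. The adhesion gene CNTN1 fell from 746 and 524 to 384 and 40 (edgeR adjusted p = 0.0145; 0.52 with TMM, 0.952 by DESeq2 and 0.98 with robust fitting). It was 1.37-fold lower without SUPT3H replicate 2. Without parental replicate 1 or 2 no gene was called in U2OS. Without SUPT3H replicate 1 the adjusted p was 0.157 for IL17RD, 0.204 for SPRY4, 0.565 for EPHA4, 0.731 for DLG2 and 0.521 for THBS1, and without replicate 2 it was 0.591 for EPHA4, 0.70 for DLG2, 0.814 for THBS1 and 0.692 for IFI44. In mESC, windows of chromosome 14 from 66297031 to 122106974 were shifted by 0.37 in knockout replicate 1 and −0.18 in replicate 2, and windows of chromosome 17 from 75537086 to 94877497 by −0.51 and 0.37. The wild-type libraries differed in the same places by 0.53 and −0.79.

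Neighbouring genes moved together in the U2OS SUPT3H libraries. The smaller SD of the window medians was 0.224, above the 0.118 reached by 100 shuffles of gene order, which excludes chance order, and the parental libraries differed by an SD of 0.064, which argues against a technical trend common to all libraries. In windows chosen by their odd-numbered genes, 79.5% of the even-numbered genes lay on the same side, as a change in copy number would give, but so would any other regional cause, so copy number stays open and untested by this value. An effect of SUPT3H on regions cannot be told apart from other changes that both libraries carry, since their windows correlated at 0.412 when set against different parental libraries, above the shuffles (0.320) and under the 0.7 such an effect was taken to need. Stretches of up to 300 genes moved in a single SUPT3H library, and in replicate 2 several of them lay along chromosome 2 between 55547292 and 242160153. No DNA measurement was used here.

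Long genes were higher in the mESC libraries labelled knockout, with a Spearman correlation across genes of 0.207 between span and fold change, and 0.111 to 0.194 in the 4 pairs of a knockout and a wild-type library. A length trend that arises between libraries whatever their group is argued against by the correlations within groups, of which the larger in size was −0.0536 (0.0536 without its sign). Expression level does not account for it either, as the correlation was 0.281, 0.319 and 0.293 in genes of low, middle and high mean count. A difference in handling between the groups, GC content, for which no mouse genome was used here, and a slower or faster passage of RNA polymerase after loss of Supt3h all stay open. Genes are not independent replicates, so no p is given.

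Fold changes of the changed cells over their controls tended weakly to go the same way in both lines, although SUPT3H was raised in U2OS and its gene targeted in mESC. Of the shared genes, 39.2% went opposite ways. Read as more over less SUPT3H by the labels, the correlation was −0.147, opposite to a response that follows the level of SUPT3H, but it ranged up to −0.0449 with a library left out, so such a response is not excluded. The Spearman correlation of 0.138 became 0.109 given gene span, 0.116 given mean count and 0.0402 given both, so span alone accounted for little of it. In U2OS the correlation of fold change with span, 0.0933, was under those between libraries of a group (0.109 and 0.201), and a length trend in both lines stays open. Differences between libraries of a group gave correlations between the lines of up to 0.0864 in size, too close to the observed one to settle the matter.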
